A study of Mus musculus with 3 samples.

How the data were processed

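Gene expression was measured in MigA9 cells treated with 2.5 µM DB818 for 6, 12 or 24 h, against untreated cells, on 3 two-colour Agilent mouse arrays, 1 for each time. The treated sample was labelled with Cy5 and the untreated one with Cy3 on every array, per the labels. The authors scanned the arrays and extracted signals with Agilent Feature Extraction 9.1.3.1. The scanner files hold foreground and background intensity for each channel, per the file headers. The deposited value file holds the scanner's log10 ratio, treated over untreated, and its largest difference from the ratio in the scanner files was 0. Ratios computed here are log2 ratios of the deposited intensity values.

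Mean foreground and median background signals were corrected with normexp (offset 50) and normalised by loess within each array in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the data-table package), with no scaling between arrays. Control spots and spots the scanner marked as outliers (37, 36 and 52 on the 6, 12 and 24 h arrays) were left out. Spots of a probe were averaged, and a gene's value was the mean of its probes that were well above background in both channels and not saturated. Of 41174 probes, 40.6, 40.6 and 41.0% met this on background in both channels. A further 1723, 1686 and 1890 did so in Cy5 alone and 255, 288 and 339 in Cy3 alone, and 38, 44 and 46 were saturated in Cy5. These gave bounds. Gene names came from a RefSeq table by accession (22864 probes), symbol (6732) or synonym (3498), and the file's name was kept for 8080 probes. Most ratios were close to 1, with 97.4, 97.9 and 95.8% of genes within 1.25-fold at 6, 12 and 24 h. The offset of 50, added to both channels, draws the ratios of dim genes toward 1, so these sizes are compressed. Median Cy3 signals over all probes were 78.2, 79.2 and 79.3, with backgrounds of 41, 42 and 42. With plain background subtraction 8 genes, in place of 4, were at least 2-fold higher at 24 h, and 6, in place of 4, were lower.

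The ratios at single times, the change between 6 and 24 h and the overlaps were described by size without a test, since no time was repeated. The mean over the 3 times was tested against 0 with limma (intercept, eBayes, 2 residual degrees of freedom, prior 4.82), with Benjamini-Hochberg adjustment at 0.05, on the 10956 genes measured on all arrays. Errors are standard errors from that fit. Of 35 gene lists written from general knowledge, those with at least 5 measured genes were given the percentile of their median among 10000 random lists matched on intensity in 20 bins. Over the 3 times they were tested with camera at a preset correlation of 0.01, adjusted over the lists. The alternative, a correlation estimated for each list, rests on 3 arrays with 2 residual degrees of freedom. With it camera's smallest adjusted p over all 28 lists was 0.98, so a missing call in that setting cannot tell against a list. The preset 0.01 lay below the estimates for the lists called down: 0.44 (primary granules), 0.086 (monocytes), 0.66 (glycolysis and hypoxia) and 0.18 (lysosome). The p-values from the preset value may therefore be too small, and a call that rests on it alone is weak. Counts adjusted over the list alone correct the same p-values within that list. The channels of different arrays were compared after quantile normalisation of each channel. Figures and summaries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

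Named genes were, for each time, the 10 highest and 10 lowest ratios among genes with an established symbol whose probes shared a sign. For the mean they were the 10 highest and 10 lowest past the threshold with 1 sign on all arrays, and for the change between 6 and 24 h the 5 highest and 5 lowest. The 3 largest bounds each way, up to 6 members of each list with the largest mean ratios, and 14 genes fixed by name were added. Comparisons, lists, tests and this rule were chosen before the data were examined. Alternatives covered background correction, normalisation, the filter on dim probes, the choice of probe, thresholds, array weights, leaving out each array and the correlation between genes.

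The tests were run on simulated data. All 200 planted genes at 1.25-fold, 1.5-fold and 2-fold (67, 67 and 66) were recovered, with 14 false calls among 214. Camera recovered 2 of 2 shifted lists and called 0 of 20 unchanged ones, and 5.0% of 200 unchanged lists fell outside the central 95% of random lists. The noise was drawn for each gene independently, without correlation between genes or dye bias. In the data the estimated correlation was 0.44 for primary granules and 0.66 for glycolysis and hypoxia. These error rates therefore need not hold for the real lists. Spike-in spots were not used, since 26, 38 and 27 of 330 were above background in Cy3 and 9, 5 and 6 in Cy5.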

Results

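RNA from MigA9 cells, a mouse hematopoietic line that was transformed by the homeobox transcription factor Hoxa9 and depends on medium conditioned with GM-CSF, was compared with and without DB818, a ligand of the DNA minor groove that has been studied as an inhibitor of HOXA9 binding to DNA. The cells received 2.5 µM DB818 for 6, 12 or 24 h, and RNA of each treated culture (Cy5) was hybridised with RNA of untreated cells (Cy3) to 1 array per time. The 3 arrays carried 41174 probes for 27389 genes, and 11447, 11475 and 11565 genes were well above background in both channels at 6, 12 and 24 h, with 10956 measured at every time. No time had a second array and the dyes were never swapped, so the number of arrays limits the precision. The scatter of the log2 ratio between repeated spots of 1 probe was 0.046, 0.034 and 0.051 (SD) on the 6, 12 and 24 h arrays, which covers spotting and scanning only. Values below are log2 ratios of treated to untreated cells unless a fold is named.

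The question at 6 h was which transcripts differed soon after exposure. Of the 10 lowest ratios among named genes, 5 belonged to genes of hypoxia and glycolysis. Bnip3, a hypoxia-induced mitophagy receptor, was 2.05-fold lower. Eno1 and Pfkl, both glycolytic enzymes, stood at -0.68 and -0.67, and Egln3 and Ankrd37, which are induced by hypoxia, at -0.60 and -0.57. Elane, the neutrophil elastase of primary granules, stood at -0.58, and Dhrs11, the non-coding RNA Rmrp, Rab10os and Selenbp1 lay between -0.63 and -0.57. The highest ratios were those of Lmnb1 (0.94), which encodes lamin B1, Metrn (0.87), the linker histone H1f5 (0.83) and Bach1 (0.76), a repressor of heme-responsive genes, followed by Usp42, Tatdn2, Hmg20b, Tnrc18, H2ac4 and Spop, between 0.72 and 0.62. In all, 0 genes were at least 2-fold higher and 2 at least 2-fold lower (Bnip3 and, lower still at -1.38, the clone AK036026, measured on this array alone and named after its value was seen), and 15 and 9 were at least 1.5-fold higher and lower. From Agilent's own processed signals, 5 genes were at least 2-fold higher and 24 lower. With 1 array there is no replicate check on any of these sizes.

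At 12 h the highest ratio was that of Csn1s2a, a casein of milk (2.14-fold higher), followed by Oscp1 (1.89-fold) and by Timp2, an inhibitor of metalloproteinases (0.69). Gja5, Prss16, Arap3, Tmem53, Mettl27, Stap2 and the pro-apoptotic gene Bmf lay between 0.68 and 0.61. Spp1, which encodes osteopontin, was 1.86-fold lower, the deiodinase Dio2 stood at -0.72, the retinaldehyde dehydrogenase Aldh1a3 at -0.69, Glyat at -0.68, the microsomal glutathione transferase Mgst1 at -0.61 and the proton-sensing receptor Gpr65 at -0.59. Csn1s2a was the 1 gene at least 2-fold higher. The 3 genes at least 2-fold lower were Hgf (-5.92), Olfr94 (-2.12) and Scml2 (-1.44). Each of these, like Lamb1 (-0.96), rested on 1 probe that was measured on the 12 h array alone, and among genes measured on all 3 arrays 0 were at least 2-fold lower. At 1.5-fold, 12 genes were higher and 11 lower, and from Agilent's processed signals 13 and 36 were at least 2-fold higher and lower.

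At 24 h the differences were wider. Csn1s2a was 3.46-fold higher and Oscp1 2.47-fold, and Gsn, the actin-severing protein gelsolin, and Derl3, a factor of endoplasmic-reticulum-associated degradation, were 2.06-fold and 2.05-fold higher. The neuropeptide gene Gal (0.94), Stap2 (0.84), Gja5 (0.81), Prss16 (0.79), Bmf (0.78) and Tbc1d10c (0.77) came next. Spp1 was 2.39-fold lower, Mpo, the myeloperoxidase of primary granules, 2.27-fold and Aldh1a3 2.12-fold. Cabcoco1 was 2.00-fold lower at 24 h, with ratios of -0.04 and -0.05 at 6 and 12 h. Dio2 (-0.89), the myelin protein gene Pmp22 (-0.85), the beta-glucan receptor Clec7a (-0.84), the maltase Mgam (-0.83), Glyat (-0.79) and Mgst1 (-0.76) completed the 10 lowest. Altogether 4 genes were at least 2-fold higher and 4 lower, and 39 and 26 at least 1.5-fold. From Agilent's processed signals the 2-fold counts were 36 and 63, and with median centring in place of loess 7 and 58.

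**Figure D1:**
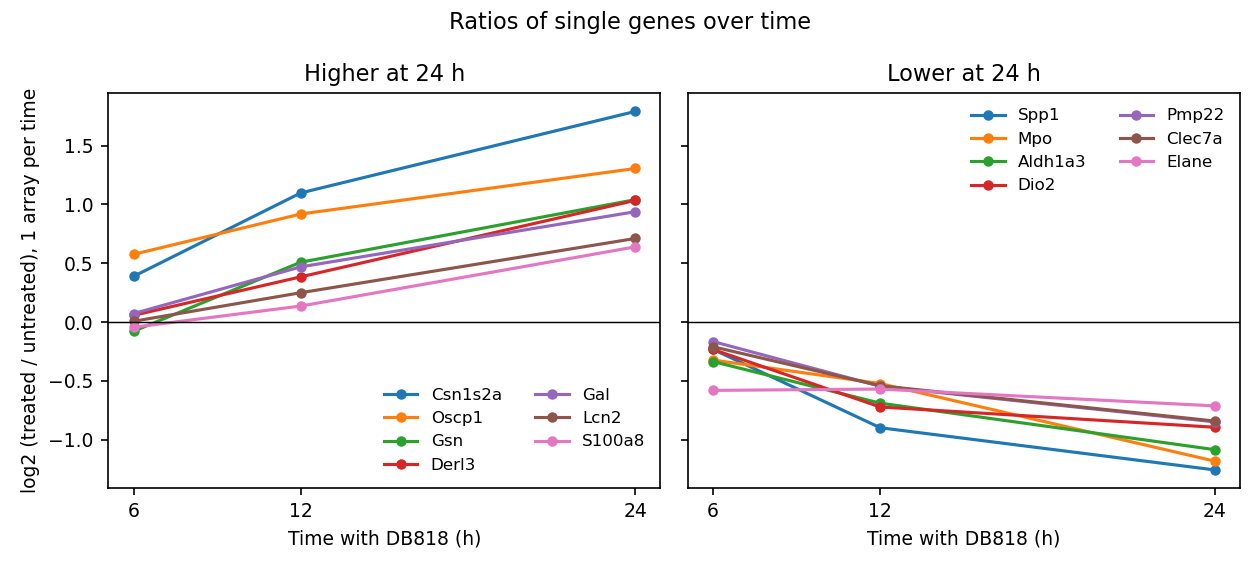
Log2 ratio of DB818-treated to untreated cells (vertical axis) against hours of treatment (horizontal axis) for 14 genes, 1 array per time and therefore no error bars. Csn1s2a climbed from 0.39 at 6 h to 1.79 at 24 h and Spp1 went from -0.23 to -1.26, while Elane stood at -0.58 already at 6 h.

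Probes above background, or below saturation, in 1 channel only gave bounds, which are open to dye bias. Those of dim probes are also drawn toward 1 by the offset. Csn2, the beta casein, had ratios of 0.02 and 0.43 at 6 and 12 h. At 24 h its treated channel was saturated, and it was at least 1.49-fold higher. Every bound for a treated signal over an untreated signal not well above background was under 1.5-fold at 6, 12 and 24 h, with Taf2, Clip4 and B3gnt5 having the largest (at least 1.38-fold, 1.35-fold and 1.39-fold). In the other direction Gpr176 and Krt2 were at least 1.93-fold and 1.86-fold lower at 6 h, and Spata3 and St6gal1 at least 5.15-fold and 2.19-fold lower at 12 h, again each on 1 array. At 24 h the largest bound for a lower signal, at least 2.84-fold, came from a probe without an established gene symbol, and among named genes Oc90 came first (at least 1.26-fold lower).

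The mean ratio over the 3 times asked which genes had a mean log2 ratio away from 0. Csn1s2a had the highest mean (1.09 ± 0.22, SE, n = 3 arrays, limma adjusted p = 0.015), and it was higher on 3 of 3 arrays, as were Oscp1 (0.93 ± 0.12, adjusted p = 0.0050), Timp2 (0.64 ± 0.05, adjusted p = 0.0034), Gja5 (0.64 ± 0.07), Prss16 (0.63 ± 0.06), Bach1 (0.61 ± 0.05), the vesicular GABA transporter Slc32a1 (0.56 ± 0.05), Stap2 (0.56 ± 0.10), Arap3 (0.56 ± 0.08) and Metrn (0.55 ± 0.09). The genes with the lowest means were Spp1 (-0.79 ± 0.17, adjusted p = 0.016), Aldh1a3 (-0.70 ± 0.12, adjusted p = 0.0094), Mpo (-0.67 ± 0.14, adjusted p = 0.017), Elane (-0.62 ± 0.04, adjusted p = 0.0034), Dio2, Glyat, Mgst1, Gpr65, the quiescence factor Klf2 (-0.55 ± 0.05) and Adgre5, all lower on 3 of 3 arrays. Of 10956 genes, 2199 rose and 861 fell at a false discovery rate of 0.05. These 3060 genes were 27.9% of those tested, the share beside which counts of list members below are to be read. Most of these changes were small: the median size of the 3060 was 1.12-fold, and 12 reached 1.5-fold. The test measures the spread between 3 times, which stand in for replicates, and a dye bias of a gene that is the same on each array adds to its mean. If the untreated RNA was 1 preparation, its own deviation is also common to the 3 ratios. Neither enters the spread, so the stated false discovery rate need not hold, least of all for small changes. The 12 h array, which had the highest weight when arrays were weighted (4.40, against 0.42 and 0.54), weighed most on the count. It is the middle time, and its ratios correlated with those of 6 and 24 h at r = 0.69 and 0.79, against 0.54 between 6 and 24 h. Since change with time counts as error here, that weight need not reflect a better array. Without the 12 h array, and with 1 residual degree of freedom fewer, 409 genes rose and 143 fell. Csn1s2a (1.09), Spp1 (-0.74), Dio2 (-0.56) and Stap2 (0.53) were then no longer past the threshold, with means about as large as before. Without the 24 h array 1498 rose and 573 fell. From Agilent's processed signals 590 rose and 640 fell, and with median centring without loess 4140 rose and 4483 fell, so the excess of rises rested on the scaling. From Agilent's processed signals Spp1 (-0.98), Mpo (-0.65), Csn1s2a (1.18), Stap2 (0.59) and Metrn (0.58) lost their call with means about as large or larger. Mpo (-0.17) and Adgre5 (-0.13) lost it with median centring, and Aldh1a3 (-0.30) without the filter on dim probes. Of 83 genes that passed among those named for the mean and larger or chosen list members, 30 lost the call without the 12 h array and 28 from Agilent's processed signals, and 0 of them changed direction. The median ratio of all measured genes was 0.03, 0.02 and 0.03 at 6, 12 and 24 h, not 0.

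For the change between 6 and 24 h, in which a constant dye bias cancels, the ratio of Csn1s2a was 2.64-fold higher at 24 h than at 6 h, that of Gsn 2.17-fold and that of Bnip3 2.02-fold. Derl3 (0.98) and Gal (0.87) followed. Lmnb1 (-1.05) and Spp1 (-1.02) were at least 2-fold lower at 24 h than at 6 h, followed by Cabcoco1 (-0.96), Mpo (-0.86) and Mgam (-0.80). For Bnip3 and Lmnb1 the difference came from 6 h ratios of -1.03 and 0.94 that stood at -0.02 and -0.11 by 24 h. The counts were 3 genes up and 2 down at 2-fold, 24 and 14 at 1.5-fold, and 31 and 15 at 2-fold from Agilent's processed signals. No test could be made of 1 array against another.

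Most genes at least 1.5-fold changed at 12 h were so at 24 h. Csn1s2a was the 1 gene at least 2-fold higher at both 12 and 24 h, and 0 genes passed 2-fold in the same direction at 6 h and at either later time or at all 3 times. At 1.5-fold, among the 10956 genes, 10 of the 11 genes higher at 12 h were also higher at 24 h (0.038 for independent lists) and 6 of the 7 lower at 12 h were also lower (0.015 for independent lists). Between 6 and 24 h 0 genes passed 1.5-fold at both times in either direction, although H2ac4 (0.62 and 0.51), Bach1 (0.76 and 0.47) and Eno1 (-0.68 and -0.49) kept their sign with smaller sizes. Across genes, which are not independent replicates, the ratios correlated at r = 0.69 between 6 and 12 h, 0.79 between 12 and 24 h and 0.54 between 6 and 24 h. A simulation of unchanged arrays with a shared control gave 0.50 for each pair. That value was fixed by construction, since the control and the treated sample were given equal noise. The covariances were 0.011, 0.015 and 0.010 against 0.0057, 0.0062 and 0.0066 in the simulation, which follow from the same setting and the spread of each array. The simulation therefore does not estimate how much a shared control adds. Whether the untreated RNA was 1 preparation is not given in the sources used here, and gene-specific dye bias also enters each pair.

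As a background, the untreated channels were compared with one another between arrays. Bnip3 and Ankrd37 stood out in untreated cells too: the untreated log2 signal of Bnip3 was 9.66 on the 6 h array, 8.20 on the 12 h array and 8.65 on the 24 h array, and that of Ankrd37 was 8.26, 6.55 and 6.67. In treated cells the values for Bnip3 were 9.77, 9.27 and 9.74, and those for Ankrd37 were 8.69, 7.07 and 7.35. Between untreated channels 67 genes differed at least 2-fold for the 6 and 12 h arrays, 85 for 12 and 24 h and 83 for 6 and 24 h. Of these, 66, 85 and 82 differed at least 2-fold in the same direction between the treated channels of the same arrays.

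**Figure D2:**
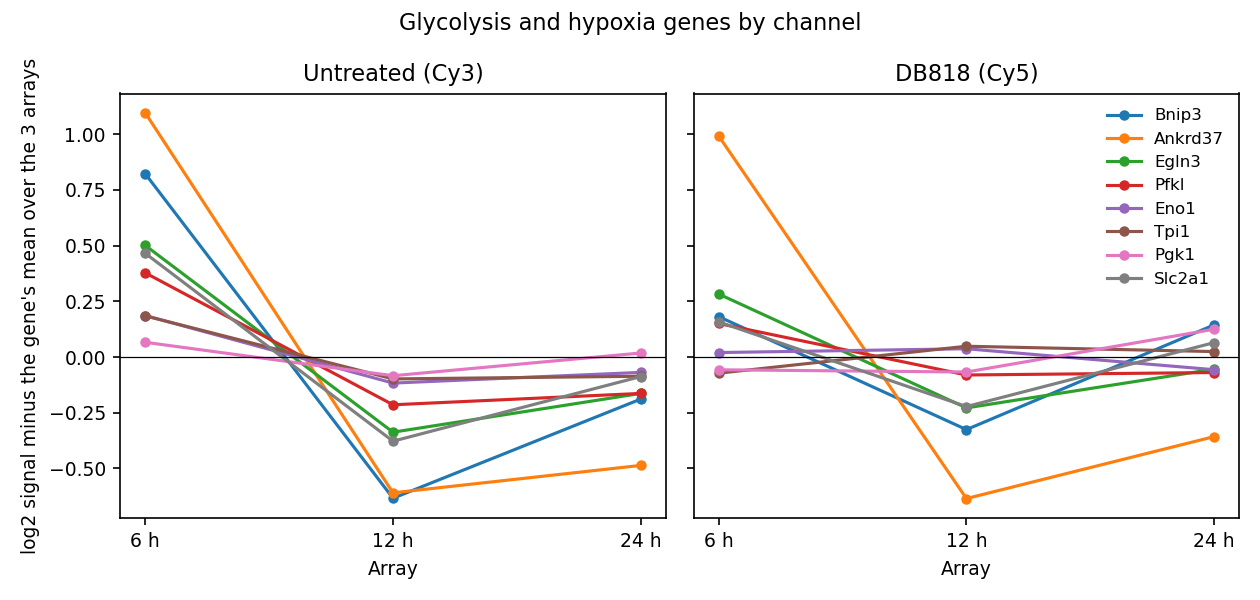
Quantile-normalised log2 signal of 8 genes of glycolysis and hypoxia, minus each gene's mean over the 3 arrays (vertical axis), in untreated cells (left) and DB818-treated cells (right) on the 6, 12 and 24 h arrays. The untreated signal of Bnip3 was 9.66 on the 6 h array against 8.20 and 8.65 on the others, and the signal of Ankrd37 was highest on the 6 h array in both channels.

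Hoxa9 itself, whose signal includes the transforming copy if the probe matches it, rose (0.35, 0.21 and 0.11 at 6, 12 and 24 h, mean 0.22 ± 0.05, limma adjusted p = 0.016, a call lost without the 12 h array and from Agilent's processed signals, at means of 0.23 and 0.27). It was the 1 member that passed among 8 measured Hox genes and cofactors, of which 0 fell and 7 did not pass (1 and 0 when adjusted over the list alone). Meis1, Flt3 and Cd34 were not well above background in both channels on any array. Of 22 measured genes reported to be activated by Hoxa9 and Meis1, 8 rose, 6 fell and 8 did not pass (9 and 6 when adjusted over the list alone). The kinases Kit (0.32 ± 0.03), Lyn (0.25 ± 0.03) and Lck (0.33 ± 0.06, but -0.02 with median centring) and the surface protein Cd47 (0.27 ± 0.04, but 0.07 from its brightest probe) rose, and the kinase Pim1 (-0.26 ± 0.03), the transcription factor Sox4 (-0.21 ± 0.06) and Myb (-0.21 ± 0.04), a regulator of progenitor growth, fell. Camera gave an adjusted p of 0.88 for this list, upward. Among 12 markers of hematopoietic stem and progenitor cells, 4 rose, 3 fell and 5 did not pass (5 and 4 over the list alone), with Kit, Egfl7, Tal1 and Runx1 up. With median centring Tal1 (0.02), Runx1 (0.01) and Myb (-0.10) lost their call. Camera pointed down (adjusted p = 0.94) where the list's median and mean were 0.02 and 0.04, and likewise for the Hox list (adjusted p = 0.94, median and mean 0.03). Camera compares the mean test statistic of a list with that of all other genes, and the median ratio of all measured genes lay above 0 at each time. Its direction down, here and for the lists below, therefore need not conflict with a mean just above 0. Neither Myc, with a mean of -0.07 ± 0.03 (adjusted p = 0.13; 0.09 with median centring), nor Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, at 0.03 ± 0.06 (adjusted p = 0.74; -0.09 with median centring), passed. Without the 12 h array Lck (0.32), Sox4 (-0.23), Myb (-0.17), Egfl7 (0.25), Tal1 (0.23) and Runx1 (0.20) were no longer past the threshold, with means close to those of all arrays.

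Genes of primary granules and promyelocytes fell as a group with the preset correlation between genes (camera adjusted p = 0.00026), but not with an estimated one (adjusted p = 0.98 with an estimated correlation). Of 15 measured members 7 fell, 0 rose and 8 did not pass (7 and 0 when adjusted over the list alone). Mpo, Elane and the granule protease activator Ctsc (-0.24 ± 0.04, but -0.01 with median centring) were among those that fell. So were the proteinase Prtn3 (-0.28 ± 0.04), Serpinb1a (-0.24 ± 0.06) and Hp (-0.15 ± 0.04), which stood at 0.04, 0.21 and 0.29 with median centring. The median of the list was -0.05, -0.08 and -0.21 at 6, 12 and 24 h, at percentiles 10.9, 0.97 and 0.0 among 10000 random lists of like intensity. With median centring in place of loess the medians at 12 and 24 h turned to 0.14 and 0.11, both at percentile 0.0 among random lists of like intensity. That setting left ratios rising with brightness, from a median of -0.77 in the dimmest 10% of genes to 0.43 in the brightest 10% at 24 h.

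Genes of secondary granules and mature neutrophils moved in both directions. Of 32 measured members 6 rose, 9 fell and 17 did not pass (9 and 9 over the list alone). The integrin Itgam rose (0.38 ± 0.03), and Mgst1, the collagenase Mmp8 (-0.31 ± 0.07) and the chitinase-like Chil3 (-0.36 ± 0.04, but 0.10 with median centring) fell, as did Ngp (-0.13 ± 0.03, but 0.05 with median centring). At 24 h the iron-binding lipocalin Lcn2 (0.71), the calprotectin genes S100a8 (0.64) and S100a9 (0.55) and the decoy receptor Il1r2 (0.61) were higher, with 6 h ratios of 0.01, -0.04, -0.18 and -0.17. Ngp, S100a8, S100a9 and Il1r2 were chosen after their values were seen. Neither Lcn2 nor these last 3 passed the test of the mean, nor did Camp (0.00 ± 0.07) or Ltf (0.01 ± 0.07), both encoding antimicrobial granule proteins. The list's median was -0.07 at 6 h (percentile 0.010; with median centring 0.06, at percentile 1.91), 0.03 at 12 h (55.9) and 0.15 at 24 h (100; with median centring 0.18, at percentile 57.2). The camera call over the 3 times was not significant (adjusted p = 0.77), and its direction was down while the list's median and mean over the 3 times were 0.04 and 0.01.

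Genes of monocytes and macrophages fell as a group with the preset correlation (camera adjusted p = 0.0024). The estimated one (camera adjusted p = 0.98) again cannot decide this, so this call too rests on the preset value. Of 23 members 9 fell, 4 rose and 10 did not pass (12 and 4 over the list alone). The transglutaminase subunit F13a1 (-0.46 ± 0.09, but 0.02 with median centring), the monocyte regulators Irf8 (-0.33 ± 0.05) and Spi1 (-0.29 ± 0.04), the chemokine receptor Ccr2 (-0.27 ± 0.05) and the growth factor receptor Csf1r (-0.13 ± 0.03) fell, and Tlr4 rose (0.27 ± 0.04). Csf1r lost its call from its brightest probe (-0.08), without the filter on dim probes (-0.10) and without the 12 h array (-0.13). The median was -0.01, -0.06 and -0.17 at 6, 12 and 24 h (percentiles 7.1, 0.060 and 0.0). With median centring the medians at 12 and 24 h were 0.02 and 0.01 (percentiles 3.95 and 0.71). Of 5 genes of dendritic cells and MHC class II 2 fell, 0 rose and 3 did not pass (3 and 1 over the list alone), and the list lay at percentile 1.80 at 12 h and 0.65 at 24 h (61.0 and 38.5 without the filter on dim probes, and 9.97 at 24 h with median centring). Camera did not call it (adjusted p = 0.070, and adjusted p = 0.98 with an estimated correlation). Its largest member was the invariant chain Cd74 (-0.38 ± 0.04, adjusted p = 0.0039).

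Genes of glycolysis and hypoxia were lowest at 6 h, with a median of -0.21 (percentile 0.0 of random lists), -0.03 at 12 h (0.70) and 0.00 at 24 h (20.7). Of 31 members tested over the 3 times 7 fell, 2 rose and 22 did not pass (7 and 2 over the list alone). Eno1 (-0.51 ± 0.06), Pfkl (-0.42 ± 0.07) and Egln3 (-0.33 ± 0.08) fell, and Pgam1 (-0.41 ± 0.04), Pkm (-0.34 ± 0.04) and Tpi1 (-0.25 ± 0.07) fell as well but stood at 0.13, 0.02 and 0.23 with median centring. The glucose transporter Slc2a1 had ratios of -0.07, 0.44 and 0.42 and did not pass (adjusted p = 0.082), and it was chosen, like Tpi1, after its values were seen. Camera gave an adjusted p of 0.00096 for the list, with adjusted p = 0.98 with an estimated correlation, 0.25 without the 6 h array and 0.081 without the filter on dim probes. With median centring the 12 h median was 0.10 (percentile 5.85).

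A minority of lysosomal genes fell, each by little: 7 of 28 members fell, 1 rose and 20 did not pass (7 and 1 over the list alone). Among those that fell were Gla (-0.19 ± 0.03) and Hexa (-0.17 ± 0.04, but 0.28 with median centring). Gla lost its call with median centring (-0.01) and without the filter on dim probes (-0.10). The list's median was -0.04, -0.02 and -0.06 at 6, 12 and 24 h (percentiles 0.54, 8.4 and 0.17; with median centring 0.18, 0.12 and 0.14, at percentiles 1.11, 0.26 and 0.070), and camera called the list down with an adjusted p of 0.0014, but adjusted p = 0.98 with an estimated correlation, and it called the list up with median centring (adjusted p = 0.020). Over the 28 lists that could be tested by camera, 0 rose and 4 fell with the preset correlation. With the estimated one 0 passed and the smallest camera adjusted p was 0.98, so that setting could not tell the lists apart. The preset correlation of 0.01 lay below the estimate for each list called down, so the p-values it gave may be too small.

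**Figure D3:**
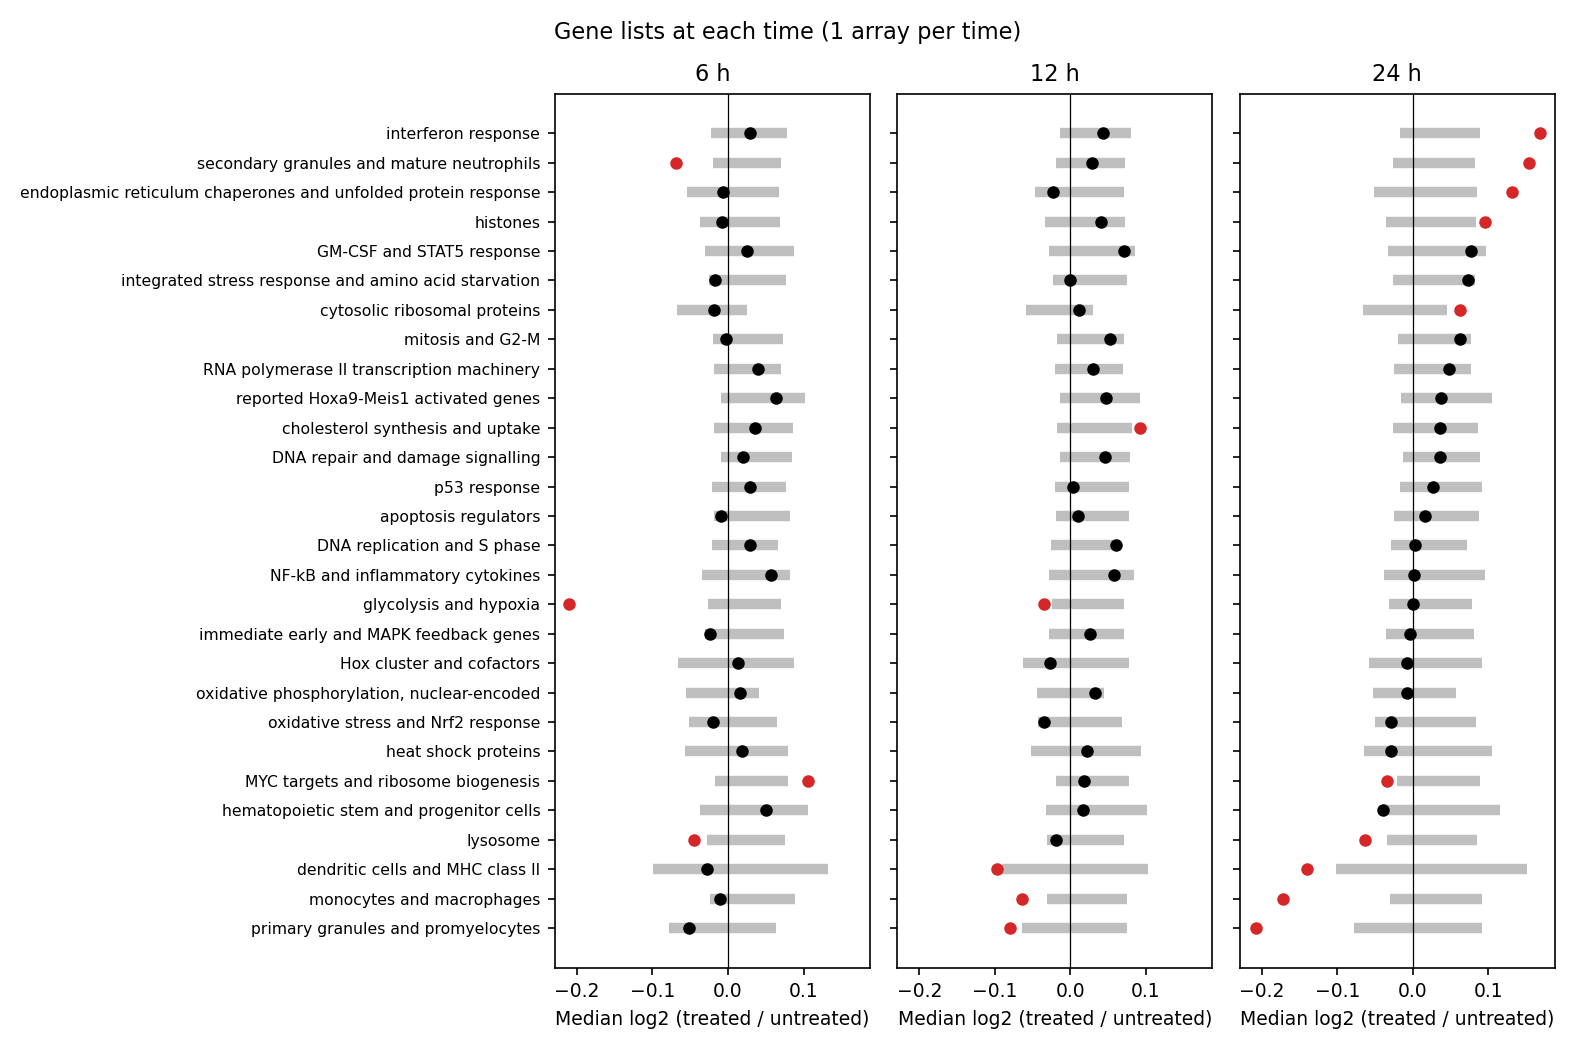
Median log2 ratio (horizontal axis) of the 28 gene lists with at least 5 measured genes at every time, at 6, 12 and 24 h, 1 array per time. Dots are list medians, red where they lie outside the grey bar, which spans the central 95% of 10000 random lists of like intensity. Glycolysis and hypoxia stood at -0.21 at 6 h, and interferon response at 0.17 and primary granules at -0.21 at 24 h (with median centring 0.0047 and 0.11, at percentiles 96.6 and 0.0).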

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

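The tests in this part were chosen after the result was seen, except that of the untreated channel's move for genes changed at 24 h. The difference between times was not tested for any result in this part, since each time had 1 array.

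Genes whose ratio or list median lay on opposite sides of 0 at 6 and 24 h stood out. The list of secondary granules and mature neutrophils had a median of -0.068 at 6 h (percentile 0.010; with median centring 0.06, at percentile 1.91) and 0.15 at 24 h (percentile 100; with median centring 0.18, at percentile 57.2). The list of MYC targets and ribosome biogenesis had 0.11 at 6 h (percentile 99.8) and -0.034 at 24 h (percentile 0.72; 0.15 with median centring, at percentile 6.78). Il1r2 went from -0.17 to 0.61, and Lmnb1 from 0.94 to -0.11.

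The first pattern weighed was the set of 62 genes measured on all arrays and at least 1.5-fold changed at 24 h, such as Csn1s2a and Spp1. A dye bias that is the same on every array was argued against by their median move from 6 to 12 h of 0.25 in the direction of the 24 h ratio (quartiles 0.18 to 0.33, 60 of 62 in that direction). Noise of the 24 h array was argued against by the same move, which does not use that array and in which a shared control cancels, since 96.8% of the genes went in that direction where noise gives about 50%. In the direction of the 24 h ratio, the median move from 6 to 12 h was -0.036 for the untreated signal and 0.22 for the treated one. The former equals 14.5% of the ratio's median move in size, a quotient of medians from differently scaled values. Differences between these arrays were largely common to both channels across genes (r = 0.89), so the figure cannot divide the ratio's move between the channels. Dye effects that differ between arrays, and time in culture or vehicle if the untreated cells were not matched, stay open.

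The second pattern was the low ratio of glycolysis and hypoxia genes, such as Bnip3 and Pfkl, at 6 h. A constant dye bias was argued against, for the list as a whole, by its median change from 6 to 24 h of 0.19 (percentile 100). Members with a steady ratio over time are not covered by that change. The untreated signal of the list on the 6 h array exceeded its mean on the other arrays by 0.15 (median, percentile 100), while that of the treated cells differed by 0.03 (percentile 76.5). Single genes differed from that median. Treated Bnip3, Ankrd37, Pfkl (9.419, 9.188 and 9.199 at 6, 12 and 24 h) and Egln3 (8.821, 8.310 and 8.484) were also highest on the 6 h array. Treated Eno1 (9.935, 9.952 and 9.858) and Tpi1 (13.190, 13.311 and 13.287) were not. For the former genes part of the 6 h rise was thus shared by both channels. Across all genes the differences between arrays went largely together in the 2 channels (r from 0.84 to 0.91). An effect of the array on both channels can thus shift either signal, so these values cannot place the change in untreated or treated cells. More of these transcripts in the untreated cells of the 6 h array, for example from culture density or oxygen supply if each array had its own culture, stays open. An effect of DB818 that held them down in treated cells stays open as well.

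The third pattern was the lower primary granule genes, such as Mpo, with S100a8, S100a9, Lcn2 and Il1r2 higher at 24 h. Whether a larger share of mature neutrophils was the whole cause could not be decided. Of 32 members of the neutrophil list 5 (Mgst1, Mmp8, Adam8 and Chil3 among them) lay between -0.76 (Mgst1) and -0.40 (Chil3) at 24 h. Another 7, with S100a8, S100a9, Lcn2 and Il1r2 among them, lay between 0.33 (Ceacam10) and 0.71 (Lcn2). The 5 lower members just met the limit set against this cause after the result was seen. The list joins genes of secondary granules and of mature cells, which need not move together. A constant dye bias was argued against, for the primary granule list as a whole, by its median change from 6 to 24 h of -0.13 (percentile 0.030). That does not cover members with a steady ratio, such as Elane, whose 6 h ratio was close to its mean over all times. A partial or uneven change in maturation, and time in culture, could not be separated with 1 array for each time.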

How the results depend on the processing

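Counts limited to genes on all 3 arrays, and other folds for the change from 6 to 24 h, were chosen after the results were seen. Slide as a block was not run, since each slide held 1 array, and scaling averages between arrays leaves ratios as they were by construction. Signal over background limited the analysis to about 41.0% of probes, and the cause of the differences below was not tested except where named.

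With median centring without loess, which left ratios rising with brightness, genes at least 2-fold higher and lower were 6 and 17 at 6 h, 2 and 13 at 12 h and 7 and 58 at 24 h, 6 and 1 for the ratio's rise and fall from 6 to 24 h, and 1 lower at all 3 times. In the mean 4140 rose and 4483 fell, 11 lists were up and 0 down, 6 lists lay below and 2 above the central range at 6 h, and 3 above at 24 h. In the main setting 3 lists lay below and 1 above that range at 6 h, 4 and 2 at 12 h, and 5 and 5 at 24 h. The number expected by chance each way was 0.70, 0.75 and 0.725 at these times. Medians of opposite sign were 0.14 and 0.11 for primary granules at 12 and 24 h (adjusted p = 0.10 over the 3 times, upward), 0.057 for secondary granules at 6 h, 0.020 and 0.0074 for monocytes at 12 and 24 h (adjusted p = 0.57), -0.024 for mast cells at 12 h, 0.10 for glycolysis at 12 h (adjusted p = 0.42), 0.15 for MYC targets at 24 h, and 0.18 and 0.14 for lysosome at 6 and 24 h, a list that camera then called up in place of down (adjusted p = 0.020). Gene means of opposite sign were Prtn3 0.040, Serpinb1a 0.21, Hp 0.29, Chil3 0.10, Ngp 0.051, F13a1 0.023, Lck -0.022, Pgam1 0.13, Pkm 0.023, Tpi1 0.23, Pgd 0.16, COX2 0.16, Mcm6 0.35, Cxcl10 -0.30 and Hexa 0.28.

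From Agilent's processed signals, and equally from the series matrix, the 2-fold counts (higher and lower) were 5 and 24, 13 and 36, and 36 and 63 at 6, 12 and 24 h, 31 and 15 from 6 to 24 h, and 1 lower at all times; 590 genes rose in the mean, and 5 and 7 lists lay below the central range at 6 and 12 h. At 1.5-fold the counts were 15 and 9, 12 and 11, 39 and 26, and 24 and 14 from 6 to 24 h. At 3-fold they were 0 lower at 6 h, 0 higher at 12 h, 1 higher and 0 lower at 24 h, and 0 and 0 from 6 to 24 h, by construction of a higher threshold. Among genes on all arrays 1 was lower at 6 h and 0 at 12 h, since fewer genes were counted. Plain subtraction gave 8 higher at 24 h and 6 and 6 from 6 to 24 h. No background correction put 4 lists above the range at 12 h. The brightest probe gave 1 gene higher at 6 h, 6 lists below at 6 h and 1 above at 12 h. Probes above background in at least 1 channel gave 6 genes lower at 12 h, with 2 lists below and 1 above. Without a filter on dim probes 2 lists lay below at 12 h, 5 were up over the 3 times, and the mast cell median at 12 h was -0.0004. List means put 7 lists below and 2 above at 6 h. Array weights gave 4188 genes up and 2125 down, with Camp at -0.13. Leaving out 1 array gave 409 to 2296 rises, 143 to 957 falls and 0 to 1 lists up, lowest for genes without the 12 h array. An estimated correlation left 0 lists down, with a smallest camera adjusted p of 0.98 over all lists.

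Of the 20 genes named for the mean, 16 kept their call without the 12 h array, 15 from Agilent's signals, 18 with median centring and 19 without the filter. Of 83 genes that passed among these and larger or chosen list members, 53, 55, 56 and 74 did so, and with median centring 15 changed sign. Over the alternatives camera's adjusted p ranged from 1.15e-05 to 0.982 for primary granules, 0.000768 to 0.982 for monocytes, 4.8e-06 to 0.982 for glycolysis and 0.000249 to 0.982 for lysosome.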

Other observations

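The test of sign splits in this part was chosen after the result was seen. Over all 10956 tested genes 27.9% passed, with 2199 up and 861 down. Counts of members near these shares do not set a list apart from other genes. Among responses to cytokine signalling, 9 of 21 measured GM-CSF and STAT5 genes rose, 2 fell and 10 did not pass (10 and 3 when adjusted over the list alone): Id1 (0.51 ± 0.05), Ccnd2 (0.28 ± 0.03) and Stat5b (0.27 ± 0.03) rose and Pim1 fell. Of 24 interferon response genes 7 rose, 1 fell and 16 did not pass (8 and 1 over the list alone), with Trim30a at 0.38 ± 0.05 and Cxcl10 at 0.25 ± 0.04 (-0.30 with median centring). The interferon list had a median of 0.17 at 24 h (percentile 100; with median centring 0.0047, at percentile 96.6), and camera did not call it over the 3 times (adjusted p = 0.19). Of 21 immediate early genes 3 rose, 4 fell and 14 did not pass (4 and 4 over the list alone), with Klf2 and Dusp6 (-0.32 ± 0.05, but -0.01 with median centring) down. Of 18 NF-kB genes 6 rose, 2 fell and 10 did not pass (6 and 3 over the list alone), and the camera direction, down, was opposite to a mean of 0.03 (adjusted p = 0.88).

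Genes of DNA repair rose in 10 of 31 cases, fell in 0 and did not pass in 21 (10 and 0 over the list alone), with Gadd45b at 0.34 ± 0.03, and 10 of 39 replication genes rose, 4 fell and 25 did not pass (11 and 5 over the list alone), with E2f1 up (0.25 ± 0.04) and Mcm6 down (-0.24 ± 0.04, but 0.35 with median centring). In mitosis 7 of 37 rose, 2 fell and 28 did not pass (7 and 2 over the list alone), with Top2a (0.25 ± 0.03) and Ccnb1 (0.22 ± 0.03) up, and 7 of 24 histone genes rose, 1 fell and 16 did not pass (7 and 1 over the list alone), with H2ac4 (0.52 ± 0.04) and H4f16 (0.39 ± 0.03) up. Of 24 p53 response genes 4 rose, 1 fell and 19 did not pass (3 and 1 over the list alone), with Trp53 (0.29 ± 0.04) and Dram1 (0.26 ± 0.04) up. Of 36 genes of RNA polymerase II transcription 8 rose, 2 fell and 26 did not pass (8 and 2 over the list alone), with Polr2h (0.24 ± 0.03) up. Camera called 0 of these 6 lists, and its direction for the p53 list was down (adjusted p = 0.88) while that list's median and mean were 0.03 and 0.04. At 24 h the median of the histone list, 0.10, lay at percentile 99.0 (76.9 with median centring).

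In metabolism and stress, 2 of 23 Nrf2 genes rose, 6 fell and 15 did not pass (2 and 6 over the list alone), with Gclc up (0.33 ± 0.05) and the pentose phosphate enzymes G6pdx (-0.42 ± 0.03, but -0.01 with median centring) and Pgd (-0.28 ± 0.04, but 0.16 with median centring) down. Of 33 MYC targets 6 rose, 0 fell and 27 did not pass (5 and 0 over the list alone), with Wdr43 (0.27 ± 0.05) and Dkc1 (0.21 ± 0.04) up. Of 28 cholesterol genes 9 rose, 1 fell and 18 did not pass (10 and 1 over the list alone), and that list's median of 0.09 at 12 h lay at percentile 99.2 (94.8 with median centring). Of 21 genes of endoplasmic reticulum chaperones 3 rose, 2 fell and 16 did not pass (3 and 2 over the list alone), with a list median of 0.13 at 24 h (percentile 99.9). Pdia6 was up (0.23 ± 0.05, but 0.04 from its brightest probe). Its call was also lost from Agilent's processed signals (0.27) and without the 12 h array (0.24). Of 29 genes of the integrated stress response 4 rose, 3 fell and 22 did not pass (4 and 3 over the list alone), with Psph up (0.41 ± 0.03). For 27 apoptosis regulators the counts were 4, 3 and 20, for 15 heat shock proteins 4, 2 and 9, for 33 ribosomal proteins 4, 3 and 26, and for 36 nuclear-encoded genes of oxidative phosphorylation 8, 3 and 25, with the same numbers past the threshold over each list alone. Camera called 0 of these last 5 lists, and its direction for each was down (adjusted p from 0.77 to 0.94) while the list means were 0.02, 0.01, 0.04, 0.01 and 0.01. At 24 h the median of the ribosomal proteins, 0.06, lay at percentile 99.4 (99.9 with median centring). The mitochondrially encoded COX2, the 1 such gene measured, fell (-0.48 ± 0.03, but 0.16 with median centring). Of 4 mast cell and basophil genes 3 rose and 1 fell, with Mcpt8 up (0.35 ± 0.06) and Hdc down (-0.36 ± 0.09). Other blood lineages had 4 or fewer genes measured on all arrays: 1 of 4 megakaryocyte genes rose and 1 fell, 1 of 2 erythroid genes and 1 of 2 T and NK cell genes rose, 0 of 2 B lineage genes passed, and 0 eosinophil genes could be tested.

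Turning the sign of 1 array at a time gives 4 splits, too few for a share under 0.05: the real signs gave 3060 genes in the mean ratio, 1 of 4 splits gave as many, and the highest other gave 0.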
